A study of Homo sapiens with 18 samples.

How the data were processed

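The data are gene expression profiles of pancreatic ductal adenocarcinoma xenografts, human tumours grown in immunodeficient nude mice, whose total RNA was profiled on 18 Affymetrix human expression arrays. Each xenograft line carries 1 phenotype in the labels, either sensitive or not sensitive to MRK-003, and each line has 2 arrays, marked A and B. The labels do not say what the letters stand for, whether both arrays come from separate tumours, or whether the profiled tumours had received any compound. There were 5 sensitive lines (10 arrays) and 4 non-sensitive lines (8 arrays). The lines are numbered within their group, and no line is named.

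The deposited values are intensities of probe sets on a linear scale. They were made with RMA (robust multi-array average, which corrects background, normalizes across arrays and summarises probes), per the submitters' processing notes, whose version is not given in the sources used here. The arrays did not share one distribution, so the deposited values are not quantile-normalized over these probe sets. The 99th percentile of intensity ranged from 1204 to 2437 over arrays, and was lowest in sensitive lines 3 and 5 and non-sensitive line 2. Values were taken to log2 with no pseudocount, since all lay above 0.

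The table held 54613 probe sets. By GEO's platform annotation of 2016, 41091 of them had 1 gene symbol, 1801 had several and 11721 had none. Of those with 1 symbol, 41037 matched a human gene record (assembly GRCh38.p14, used for names alone) by gene identifier, and 0 symbols changed. Genes were not named from probe sets with several symbols, and 95 probe sets of sex-linked genes were left out. No genomic positions are given, because the build behind the array annotation is not stated. The table held 0 hybridization control probe sets, so the planned comparison of RNA integrity controls was not run.

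Arrays of one line were averaged (avearrays in limma), because the phenotype belongs to the line and the arrays of a line are not independent samples of it. For each gene the probe set with the highest mean over lines was used. A gene was kept where its line means lay above the 30th percentile of the probe sets in at least 4 lines, which left 16887 of 19740 named genes. Groups were compared with limma (lmFit and eBayes with a variance trend, two-sided) and Benjamini-Hochberg adjustment, with a threshold of 0.05. Every fold change is sensitive minus non-sensitive on the log2 scale, with its SE from limma.

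Before the data were examined, 37 gene lists (696 genes, of which 626 were named on the array and 594 tested) were fixed for the Notch pathway, gamma-secretase, other signalling pathways, pancreatic tumour states and markers of other cell types. The lists for NF-kB, NRF2 and B-cell receptor signalling were chosen with knowledge of the topics of the published study, so they are not an independent choice. Lists were compared with camera in limma with a preset correlation of 0.01 between members. Other tests were run on the same lists: camera with the correlation estimated from the data, fry, and an exact permutation test of the mean level per line over all 126 assignments of the 9 lines, whose smallest possible p is 0.00794. Fry's directional test asks whether a list's genes move, on balance, one way, its mixed test whether they change in either direction, and neither compares a list with other genes.

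The named genes follow a rule that was also fixed in advance. It takes the 12 genes with the largest change in each direction among those past the threshold. Where there are fewer, it fills up with the genes of smallest unadjusted p among those with an absolute log2 fold change of at least 1 and no overlap between the line means of the groups. For the lists of Notch receptors and ligands, Notch targets and gamma-secretase subunits it takes the 5 members of smallest p, and for each other list described the 4 members of smallest p, of which the text prints at most the first for the cell types other than ductal cells and few or none for some pathway lists.

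The likeness of arrays was measured as the Pearson correlation across tested genes, and same-line pairs were compared with different-line pairs in a permutation test with 100000 resamples of the line labels. Letters A and B were compared with limma with the line as a block. The arrays of a line were also entered as 18 arrays with the line as a random block (consensus correlation 0.58).

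The gene and list tests were tested on simulated data with the means and residual SDs of these 16887 genes, 5 and 4 lines, and 200 changed genes in each of 5 runs. The limma test called 23.6% of genes changed by 1 on the log2 scale, 66.8% of those changed by 2, 84.8% of those changed by 3 and 95.6% of those changed by 4, with 50 false calls over all runs. Camera found the shifted list in 5 of 5 runs and called 0 other lists. The simulated genes were independent of one another, which real members of a list are not. The changed genes were drawn at random from all tested genes. Some genes with large fold changes in the data had SEs well above the median of 0.33, such as 0.96 for ANPEP and 1.78 for REG4. The shares called in the simulation therefore do not carry over to such genes.

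Alternatives covered each line left out, array A or B alone, the mean of all probe sets of a gene, no filter and a filter at the 50th percentile, repeated quantile normalization, median centring, other variance models, array weights, arrays taken as independent, and every probe set tested alone. An alternative without 2 lines whose arrays correlated below 0.9 was chosen after seeing the data. Background correction from scanner files and blocks by slide were not tried, because the value table holds neither. Computations used R 4.3.3, limma 3.58.1 and statmod 1.5.0. The number of arrays, and of the 9 lines they come from, limits the precision. The median SE of a log2 fold change was 0.33.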

Results

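Gene expression was measured on 18 arrays of human pancreatic ductal adenocarcinoma xenografts to find genes whose expression goes with the response to MRK-003. This compound inhibits gamma-secretase, the membrane protease complex that cleaves Notch receptors and other transmembrane proteins. The sensitive group held 5 lines and the non-sensitive group 4 lines, with 2 arrays per line. Mean intensity per array ranged from 108 to 166 and median intensity from 28.1 to 33.1. Mean intensity per line was 146 ± 23.0 (SD, n = 5) in sensitive lines and 148 ± 18.9 (n = 4) in non-sensitive lines, a difference that an exact permutation test did not separate from 0 (p = 0.841, two-sided).

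The first comparison asked which genes differed between sensitive and non-sensitive lines. The gene with the largest fold change among those named as higher was ANPEP, which encodes aminopeptidase N, a peptidase of the cell surface. Its log2 intensity was 9.80 ± 1.99 (SD, n = 5) in sensitive lines and 5.62 ± 1.20 (n = 4) in non-sensitive lines, an 18.1-fold difference (log2 fold change 4.18 ± 0.96 SE), a sign that 1 of its 3 probe sets carried, and the log2 fold change was 1.38 with the mean of all probe sets. Other genes with higher values in every sensitive line than in any non-sensitive line included BEX2 (2.39 ± 0.58) and BEX4 (1.80 ± 0.56), members of one small gene family, and DENND5B (2.44 ± 0.65). SCARB1, a receptor for high-density lipoprotein, had a log2 fold change of 1.21 ± 0.35, and SHMT2, the mitochondrial serine hydroxymethyltransferase, of 1.16 ± 0.37. The chemokine receptor gene CCR10 (1.50 ± 0.46), the cation channel gene TRPV2 (1.45 ± 0.48), and EML1 (2.10 ± 0.73), GPX7 (1.95 ± 0.75), TM4SF18 (1.51 ± 0.44) and SPATC1L (1.16 ± 0.32) completed the 12 genes of this direction. In every non-sensitive line BEX4 and EML1 lay below the 30th percentile of the probe sets, so their fold changes are not exact, and with those values raised to that percentile the differences are 1.01 and 1.64. That percentile was 3.85 to 4.11 over arrays. The lowest non-sensitive values of GPX7 (3.39), CCR10 (3.82), BEX2 (3.88) and DENND5B (4.03) were near or below it. Their fold changes are therefore not exact either. Probe sets also disagreed in sign for DENND5B, SCARB1 and OTUD1, and with the mean of all probe sets DENND5B stood at 0.81 and SCARB1 at 0.55. Without sensitive line 1 EML1 stood at 1.39 and GPX7 at 1.25.

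A further 12 genes had lower values in every sensitive line than in any non-sensitive line. ELOVL7, a fatty acid elongase, had a log2 fold change of -2.20 ± 0.45 (SE) and HMGCS1, an early enzyme of cholesterol synthesis, of -1.18 ± 0.35. XDH, which encodes xanthine dehydrogenase, had -1.32 ± 0.24, and SRD5A1, a steroid reductase, -1.28 ± 0.32. SFN, which encodes stratifin, an adaptor protein of epithelial cells, had -1.05 ± 0.29, and the planar cell polarity gene VANGL1 had -1.08 ± 0.27. The values for LEMD1, CLIC3, TRIP6 and SYTL1 were -2.18 ± 0.48, -1.78 ± 0.35, -1.56 ± 0.45 and -1.40 ± 0.41, and those for GPD2 and OTUD1 -1.25 ± 0.32 and -1.13 ± 0.30. With array A alone CLIC3 stood at -0.56 and VANGL1 at -0.66, and with array B alone CLIC3 stood at -3.00. With the mean of all probe sets XDH, VANGL1, GPD2 and OTUD1 stood at -0.84, -0.64, -0.79 and -0.47.

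None of these 24 genes passed the test, and neither did any other. In limma 0 of 16887 genes had an adjusted p under 0.05, the smallest being 0.9999, while 477 had an unadjusted p under 0.05, 177 of them higher and 300 lower in sensitive lines. That is 2.82% of the genes, fewer than the 844 that chance alone gives on average. Line means of the groups did not overlap for 108 genes (0.640%), where chance gives 1.59%, and of these 14 were at least 2-fold higher and 21 at least 2-fold lower in sensitive lines. Leaving out sensitive line 3 put 1 gene past the threshold, SLCO1B3, a transporter gene named after its values were seen (log2 fold change -2.90, adjusted p = 0.0256 in limma, against -1.95 over all lines). The unadjusted count moved to 207 without non-sensitive line 1, to 220 without non-sensitive line 3 and to 840 without sensitive line 2. Non-sensitive lines 1 and 3 had close values where lines 2 and 4 of that group differed. Their mucin list means were 8.62 and 8.70, against 6.85 and 7.31, and their GDF15 values 11.2 and 11.6, against 6.89 and 6.72. Means were also close for epithelial junction genes (10.3 and 10.3, against 9.58 and 9.78) and proliferation (8.28 and 8.29, against 7.05 and 7.83). They were less close for the p53 and CDK inhibitor pathway (7.23 and 7.48, against 6.90 and 7.11). All tests count them as separate lines, and whether they are independent tumours was not tested. If they are not, every comparison of the groups rests on fewer than 4 independent non-sensitive lines.

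**Figure D1:**
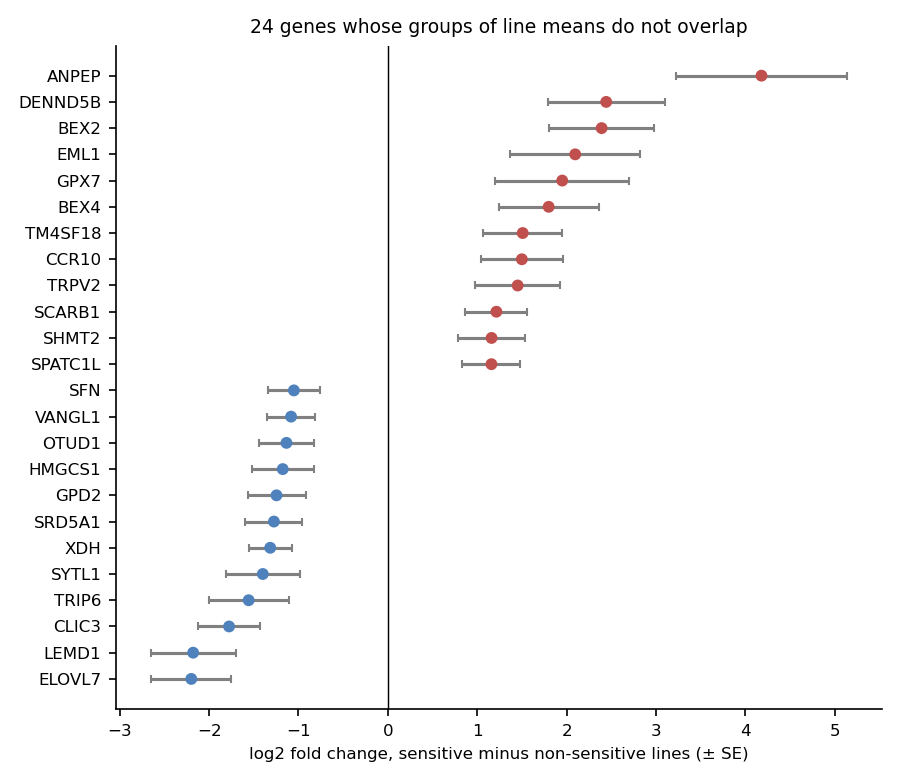
Log2 fold changes (horizontal axis, sensitive minus non-sensitive lines) of the 24 named genes, with whiskers of 1 SE, from 5 sensitive and 4 non-sensitive lines. Red points are genes higher and blue points genes lower in sensitive lines, from 4.18 for ANPEP to -2.20 for ELOVL7, and 0 of them passed the adjusted threshold.

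The Notch pathway was compared next, because the compound blocks the release of the active Notch fragment. Of the 9 Notch receptors and ligands, 5 were higher and 4 lower in sensitive lines, and the list mean was 7.07 ± 0.22 (SD, n = 5) against 7.04 ± 0.26 (n = 4). NOTCH4 had higher values in every sensitive line (6.35 ± 0.41 against 5.69 ± 0.21, log2 fold change 0.66 ± 0.25 SE), a sign that 1 of its 2 probe sets carried. NOTCH1 had 0.30 ± 0.33 and the ligand genes JAG1, DLL1 and JAG2 had -0.46 ± 0.35, -0.53 ± 0.46 and 0.23 ± 0.39, and the probe sets of NOTCH1, JAG1, JAG2 and DTX3 disagreed in sign. Among 19 Notch target genes, 11 were higher and 8 lower, with FOXA1 at -1.16 ± 0.52, DTX4 at -1.31 ± 0.76, DTX3 at 0.70 ± 0.43, HES5 at 0.27 ± 0.18 and DTX1 at 0.27 ± 0.20. When 1 line was left out, DLL1 ranged from -1.04 to -0.23, NOTCH1 from 0.063 to 0.44, JAG1 from -0.64 to -0.27, JAG2 from 0.076 to 0.53, HES5 from 0.17 to 0.38 and DTX1 from 0.16 to 0.34, and without sensitive line 1 FOXA1, DTX4 and DTX3 stood at -0.67, -0.60 and 0.44. NOTCH4 stood at 0.33 with array B alone and at 0.31 with the mean of all probe sets, and JAG1 turned to 0.044 with array A alone. The mean difference of the target list was -0.031, while its median log2 fold change was 0.075 and camera pointed upwards.

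The remaining Notch machinery also showed no difference past the threshold. Of the 21 genes of the Notch transcription complex and modifiers 11 were higher and 10 lower, and LFNG, a glycosyltransferase that modifies Notch receptors, had lower values in every sensitive line (-1.06 ± 0.33 SE), a sign that 1 of its 2 probe sets carried. RBPJ, the DNA-binding partner of cleaved Notch, had 0.78 ± 0.56, POFUT1 had 0.54 ± 0.42 and NUMB 0.45 ± 0.46. Of the gamma-secretase subunits, APH1B had -0.52 ± 0.26, PSENEN 0.30 ± 0.56, APH1A -0.22 ± 0.54, PSEN2 0.14 ± 0.36 and NCSTN 0.036 ± 0.35, a sign that 1 of the 2 NCSTN probe sets carried. Among 15 other gamma-secretase substrates 10 were lower, with CDH1 at -2.22 ± 1.11, EPCAM at -0.90 ± 0.67, APLP1 at 0.58 ± 0.39 and DCC at 0.16 ± 0.12, a sign that 1 of the 3 DCC probe sets carried. DCC lay at 3.89 to 4.32 over all lines, near the 30th percentile of the probe sets (3.85 to 4.11 over arrays). NUMB was near that level in non-sensitive lines (3.68 to 4.23) and lay at 3.32 to 5.92 in sensitive lines. Camera's adjusted p was 0.765 for receptors and ligands, for targets and for the gamma-secretase subunits, 0.895 for the transcription complex and 0.573 for the other substrates, with mean differences of 0.030, -0.031, -0.051, 0.037 and -0.22, and the sign of each but the last turned when 1 line or another was left out. The median of the subunits lay above 0 at 0.036, and 0 members of these lists passed limma, adjusted over all genes or adjusted over the list alone.

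**Figure D2:**
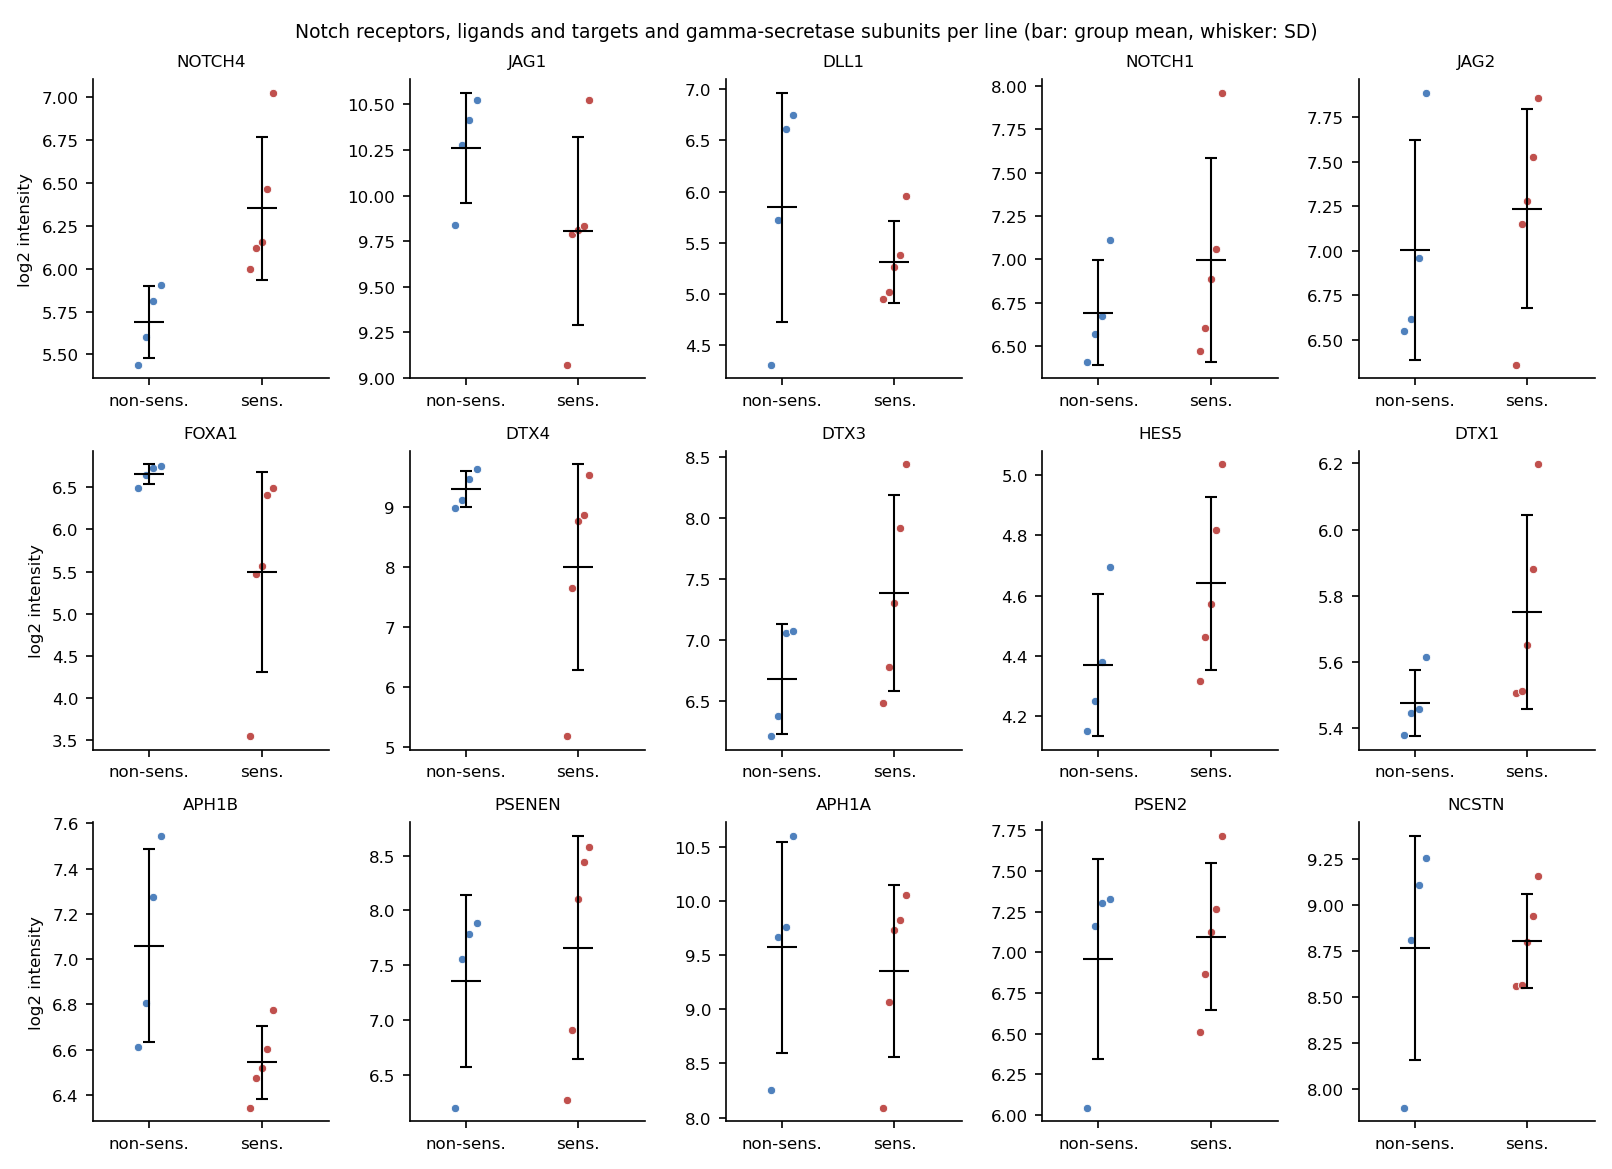
Log2 intensity (vertical axis, a separate scale in each panel) of 5 Notch receptor and ligand genes, 5 Notch target genes and 5 gamma-secretase subunit genes. Each point is 1 line (4 non-sensitive in blue, 5 sensitive in red), bars are group means and whiskers SDs. NOTCH4 is the gene whose groups do not overlap.

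Sensitive lines had lower levels of genes that mark differentiated epithelium by the preset camera test of limma, a call that did not hold with an estimated correlation (smallest adjusted p = 0.521). Of 31 tested genes of the classical pancreatic tumour type, a state of gland-like differentiation, 29 were lower, and the mean log2 level was 8.28 ± 1.82 (SD, n = 5) against 10.1 ± 1.01 (n = 4), a difference of -1.84. Members with the smallest p were the secretory protein gene AGR2 (-1.11 ± 0.34 SE), ANXA10 (-3.41 ± 1.07), VSIG2 (-1.62 ± 0.52) and CEACAM5, a surface glycoprotein gene (-3.88 ± 1.29). Of 20 epithelial junction genes 19 were lower, by -0.95 on average, among them CDH1, which encodes E-cadherin (-2.22 ± 1.11), RAB25 (-2.39 ± 1.14), TJP3 (-1.15 ± 0.55) and the desmosome gene DSP (-1.71 ± 0.90). CDH1 lay at 5.19 and 8.30 in sensitive lines 1 and 4, but at 10.5 to 11.5 in the other sensitive lines, against 11.3 to 11.9 in non-sensitive lines. RAB25 (4.54) and DSP (6.07) were also lowest in sensitive line 1, and DSP in sensitive line 5 (11.3) lay above every non-sensitive line. Genes of antigen presentation were lower in 14 of 16 cases, by -0.61 on average, with B2M, the invariant chain of class I molecules, at -0.77 ± 0.27, HLA-B at -1.51 ± 0.60, HLA-C at -1.08 ± 0.43 and HLA-DMA at -1.20 ± 0.45.

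Camera in limma with the preset correlation put these lists past the threshold, with adjusted p = 4.8e-17 for the classical list, 5.9e-08 for the junction list and 1.1e-06 for antigen presentation. With an estimated correlation the adjusted p = 0.521, 0.528 and 0.521, so none of the calls held. The exact permutation test of the line means gave p = 0.0952, 0.127 and 0.0873, each with an adjusted p of 0.755. Sensitive lines overlapped with non-sensitive lines in all 3 lists, and no member passed limma's test over all genes. Without sensitive line 1 the difference was -1.16 for the classical list (-1.84 over all lines) and -0.57 for the junction list (-0.95), and both still passed the preset camera test. With array A alone the classical difference was -2.84, and with array B alone it was -0.84, with the junction difference at -0.58.

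**Figure D3:**
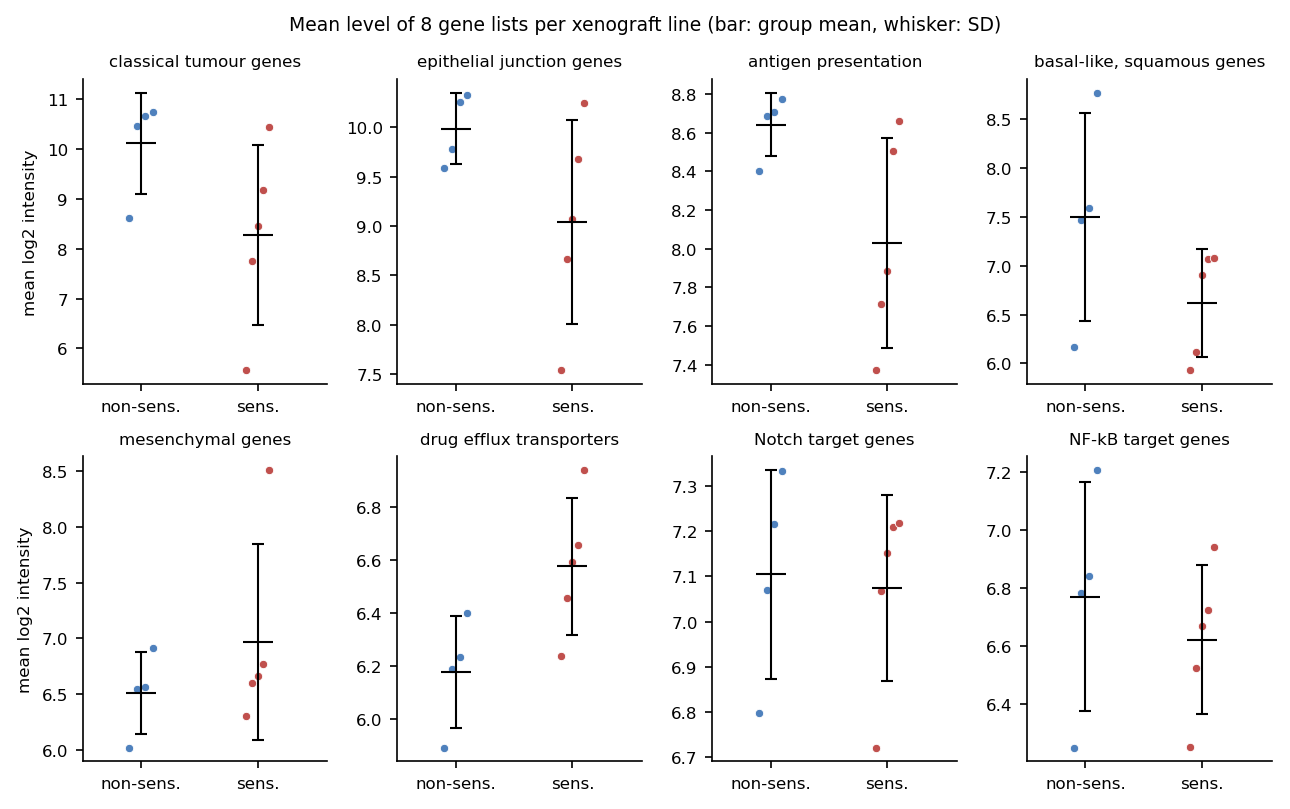
Mean log2 intensity of the members of 8 gene lists (vertical axis, a separate scale in each panel) per line, with 4 non-sensitive lines in blue and 5 sensitive lines in red. Bars are group means and whiskers SDs, and in every panel the groups overlap, including the classical tumour genes (8.28 against 10.1).

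The other lists that were lower in sensitive lines by the preset camera test brought the total to 10 of 37, with 0 higher. Genes of the basal-like and squamous tumour type, which carry keratins and other squamous markers, were lower in 15 of 21 cases by -0.88 on average (adjusted p = 2.8e-05, and adjusted p = 0.528 with an estimated correlation), with LEMD1 at -2.18 ± 0.48 (SE), DHRS9 at -2.67 ± 0.90, SPRR3 at -3.89 ± 1.33 and SPRR1B at -2.49 ± 0.89. Mucin genes averaged -0.80 (adjusted p = 0.0284, and adjusted p = 0.759 with an estimated correlation), with MUC17 at -3.03 ± 1.10, MUC1 at -1.35 ± 0.81, MUC13 at -1.43 ± 0.89 and MUC5AC at -1.76 ± 1.10. Ductal cell markers averaged -0.57 (adjusted p = 0.0281, and adjusted p = 0.528 with an estimated correlation), but SPP1, which encodes the secreted protein osteopontin, lay the other way at 2.65 ± 0.97, beside CA2 at -2.81 ± 0.94, ANXA4 at -0.99 ± 0.53 and MUC1. SPP1 lay at 8.11 to 8.56 in sensitive lines 1, 4 and 5. In sensitive lines 2 and 3 it lay at 3.93 and 4.34, against 3.93 to 4.21 in non-sensitive lines. Its other probe set had a log2 fold change of 0.12. Interferon response genes averaged -0.32 (adjusted p = 0.0153, and adjusted p = 0.759 with an estimated correlation), with IFI27 at -2.32 ± 1.07, OASL at -0.75 ± 0.38, MX1 at -0.89 ± 0.46 and RSAD2 at -0.43 ± 0.23. Cholesterol and fatty acid synthesis genes averaged -0.30 (adjusted p = 0.0284, and adjusted p = 0.597 with an estimated correlation), with HMGCS1, SQLE (-1.08 ± 0.54), IDI1 (-0.89 ± 0.46) and SREBF2 (-0.52 ± 0.36), and 1 probe set each of IDI1 and SREBF2 pointed up. With 1 line left out, the basal-like call ended without non-sensitive line 4 (-0.45) and its difference was -1.32 without non-sensitive line 2. The basal-like call also ended with array A alone (-0.39, against -1.36 with array B alone) and without the 2 lines whose arrays correlated below 0.9 (-0.33), where the ductal (-0.57) and interferon (0.097) calls ended too. The mucin call ended without non-sensitive line 1 (-0.55) or 3 (-0.53) or sensitive line 1 (-0.46), 4 (-0.72) or 5 (-0.71), and the ductal call without non-sensitive line 1 (-0.49) or 2 (-0.53) or sensitive line 1 (-0.33) or 4 (-0.40). The interferon call ended without non-sensitive line 2 (-0.39) or 4 (0.0073) or sensitive line 3 (-0.19) or 4 (-0.23), and the cholesterol call without non-sensitive line 1 (-0.16) or 3 (-0.22) or sensitive line 3 (-0.19), 4 (-0.34) or 5 (-0.25). With array B alone the mucin (-0.46), ductal (-0.22), interferon (-0.24) and cholesterol (-0.15) calls ended, and with array A alone the ductal difference was -0.93 and the cholesterol difference -0.45. The mucin (-0.73) and cholesterol (-0.27) calls ended with repeated quantile normalization, the cholesterol call (-0.22) with the mean of all probe sets and the interferon call (-0.33) with the filter at the 50th percentile, and the ductal difference was -1.04 with that filter and -0.88 with the mean of all probe sets.

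Signalling lists chosen with knowledge of the study's topics are not an independent choice. Genes of B-cell receptor signalling averaged -0.30 (camera adjusted p = 0.0153, and adjusted p = 0.521 with an estimated correlation), with 14 of 23 lower. Their members DAPP1 (-0.83 ± 0.29 SE), PLCG2 (-1.48 ± 0.58), VAV3 (-0.93 ± 0.40) and LYN (-1.54 ± 0.68) encode an adaptor, a phospholipase, an exchange factor and a kinase, which other cell types use too. NRF2 target genes, which serve the oxidative stress response, were lower in 22 of 28 cases by -0.46 on average (adjusted p = 0.0284, and adjusted p = 0.795 with an estimated correlation), with AKR1B10 at -2.56 ± 1.06, GPX2 at -2.30 ± 1.26 and AKR1C3 at -1.87 ± 1.09, while ABCC1 had 1.27 ± 0.48. NF-kB target genes did not pass camera (adjusted p = 0.765), with 16 higher and 15 lower, a mean difference of -0.15 and a median of 0.084, and with PTGS2 at -1.92 ± 0.73, CCL2 at 0.38 ± 0.17, CFLAR at -0.67 ± 0.32 and CXCL2 at -0.65 ± 0.33. The mean difference of these targets was -0.32 without non-sensitive line 2 and -0.0025 without non-sensitive line 4. NF-kB subunits and regulators averaged 0.073 (adjusted p = 0.765, and 0.0093 to 0.14 when 1 line was left out), with NFKBIZ at 1.07 ± 0.60, CHUK at 0.81 ± 0.58, NFKBIB at 0.61 ± 0.48 and LTBR at -0.60 ± 0.52, a sign that 1 of its 4 probe sets carried. Probe sets also disagreed in sign for PLCG2, CFLAR and CXCL2. The B-cell receptor call ended without non-sensitive line 4 (-0.27) or sensitive line 1 (-0.19) or 4 (-0.28), and the NRF2 call without non-sensitive line 1 (-0.35) or 4 (-0.45) or sensitive line 3 (-0.28) or 4 (-0.45). Both calls also ended with array B alone (-0.18 and -0.26) and without the 2 lines whose arrays correlated below 0.9 (-0.24 and -0.44).

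Across the 37 lists, 0 passed with an estimated correlation (smallest adjusted p = 0.521), 0 passed fry in limma (smallest adjusted p = 0.878 directional and 0.908 mixed) and 0 passed the exact permutation test (smallest adjusted p = 0.755). Adjusted over the list alone, 2 members passed limma, 1 in the basal-like list and 1 in the islet and neuroendocrine list, where over all genes 0 did. The preset camera count moved from 10 to 6 without non-sensitive line 1, to 6 without non-sensitive line 4, to 4 without sensitive line 4, and to 5 without the 2 lines whose arrays correlated below 0.9, an alternative chosen after seeing the data.

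Among lists not past the threshold, drug efflux transporters had the smallest exact permutation p (0.0317, adjusted 0.755), with a mean difference of 0.40 and 4 of 6 members higher. It passed camera without sensitive line 1 (0.43), with array B alone (0.65) and with the filter at the 50th percentile (0.54), but stood at 0.15 with array A alone. ABCC1 had 1.27 ± 0.48 (SE), ABCC4 1.10 ± 0.53, ABCG2 0.39 ± 0.35 and ABCC2 0.31 ± 0.29. Mesenchymal transition genes averaged 0.46 (0.073 without sensitive line 1, 0.30 without non-sensitive line 2, 0.10 with array B alone, and 0.82 with array A alone, where the list passed camera) with 12 of 18 higher, FN1 and TGFBI, both of the extracellular matrix, standing at 2.27 ± 1.12 and 1.63 ± 0.76, MMP2 at 1.29 ± 0.83 and MMP14 at -0.45 ± 0.30, and probe sets disagreed in sign for ABCC4 and MMP2. MMP2 lay at 10.5 in sensitive line 1 and at 5.68 to 7.06 in the other sensitive lines. FN1 lay at 12.4 and 11.1 in sensitive lines 1 and 5 and at 6.50 to 7.51 in the other sensitive lines. Progenitor and stem-associated genes averaged -0.36 (-0.52 without sensitive line 2 and -0.56 with array A alone, where the list passed camera, and -0.099 with array B alone), with CXCR4 at -1.22 ± 0.39, KLF4 at -1.17 ± 0.44, NES at 0.82 ± 0.36 and ALDH1A1 at -2.27 ± 1.17. Gemcitabine transport and metabolism genes averaged -0.13 (0.053 without sensitive line 3 and -0.28 without non-sensitive line 2), with the nucleoside transporter gene SLC29A1 at 0.92 ± 0.37, ABCC5 at -0.71 ± 0.40, NT5C3A at -0.58 ± 0.44 and SLC28A3 at 0.33 ± 0.25, and the probe sets of ABCC5 disagreed in sign. Camera's adjusted p was 0.0870, 0.219, 0.136 and 0.689 for these lists.

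The remaining pathway lists did not pass camera over all lines. Mean differences were -0.072 for proliferation, 0.093 for the TGF-beta response, 0.092 for Wnt targets and regulators, -0.0047 for the Hedgehog pathway, 0.10 for EGFR and RAS-MAPK output, -0.056 for the p53 and CDK inhibitor pathway, -0.21 for apoptosis regulators, 0.045 for hypoxia and glycolysis and -0.19 for ribosomal proteins. Camera's adjusted p ranged from 0.219 for apoptosis regulators to 0.895. The sign turned in 8 of these 9 lists, all but apoptosis regulators, when 1 line or another was left out. The apoptosis difference then ranged from -0.29 to -0.089. Without sensitive line 3 the hypoxia (0.37) and EGFR (0.36) lists passed camera upwards, the TGF-beta difference was 0.33, and the ribosomal and proliferation differences turned to 0.12 and 0.10. Without non-sensitive line 2 the proliferation list passed camera downwards (-0.34), with the hypoxia and EGFR differences at -0.25 and -0.19. The mean of the Wnt list lay above 0 while camera pointed down, the Hedgehog mean lay below 0 while its median (0.031) and camera pointed up, and the hypoxia mean lay above 0 while its median was -0.12. Among apoptosis regulators TNFSF10, which encodes the death ligand TRAIL, had -1.99 ± 0.60 (SE), CFLAR -0.67 ± 0.32, BCL2L11 -0.87 ± 0.43 and MCL1 -0.49 ± 0.48. In the hypoxia list SLC2A3, a glucose transporter gene, had 0.78 ± 0.22, BNIP3 2.48 ± 1.11, EGLN3 -1.01 ± 0.59 and NDRG1 -0.78 ± 0.60, and in the EGFR list the growth factor gene TGFA had -2.41 ± 0.91, FOSL1 1.24 ± 0.75, ERBB2 -0.65 ± 0.40 and ETV5 0.77 ± 0.55. BNIP3 lay at 6.50 to 10.3 in sensitive lines 1, 4 and 5. In sensitive lines 2 and 3 it lay at 3.85 and 3.93, against 3.47 to 4.27 in non-sensitive lines. Probe sets disagreed in sign for CFLAR, BCL2L11, MCL1 and ETV5.

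Markers of cell types other than the tumour cells showed no difference past camera's threshold either. Mean differences were 0.21 for fibroblasts and stellate cells, 0.072 for endothelial cells, -0.045 for myeloid cells, 0.011 for lymphocytes, 0.072 for liver and intestine, -0.13 for acinar cells and -0.27 for islet and neuroendocrine cells. When 1 line was left out, the endothelial difference ranged from 0.017 to 0.12 and the islet difference from -0.43 to -0.16. The fibroblast difference was 0.072 without sensitive line 1, 0.12 without non-sensitive line 2, 0.33 without sensitive line 5, 0.40 with array A alone and 0.012 with array B alone, and the sign turned in 4 of the 7 lists when 1 line or another was left out (myeloid, lymphocyte, liver and intestine, acinar). The members of smallest p in the fibroblast, endothelial, acinar and islet lists were COL5A1 (0.77 ± 0.38 SE), EGFL7 (1.03 ± 0.38), SPINK1 (-3.11 ± 1.36) and SCG5 (-2.66 ± 0.60). In the acinar and islet lists the median lay above 0 (0.046 and 0.20) against a mean below it, and the endothelial median lay at -0.010. Stroma in a xenograft comes from the mouse host, and the probes were designed for human transcripts. List means of lymphocytes (5.19 in sensitive and 5.18 in non-sensitive lines) and myeloid cells (5.06 and 5.10) lay near the median of all probe sets. That median was 4.81 to 5.05 over arrays, and the endothelial means were 5.54 and 5.47. Differences near 0 in these lists therefore say little about the amount of such cells.

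The likeness of the arrays of a line was compared with that of arrays of different lines. Arrays of one line correlated at r = 0.933 ± 0.062 across genes (SD, 9 pairs) and arrays of different lines at 0.832 ± 0.065 (144 pairs), a difference of 0.102 that no permutation of the line labels reached (p = 1e-05, the smallest that the resamples can give). Genes are not independent replicates, and the p comes from permuting the line labels over the 18 arrays. In 4 of the 9 lines both arrays were closest to each other. Of the 18 arrays 9 lay closest to an array of another line, 4 of them to one of the other group. In 2 lines the arrays correlated below 0.9 (0.802 and 0.860), and the highest correlation between different lines was 0.983.

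**Figure D4:**
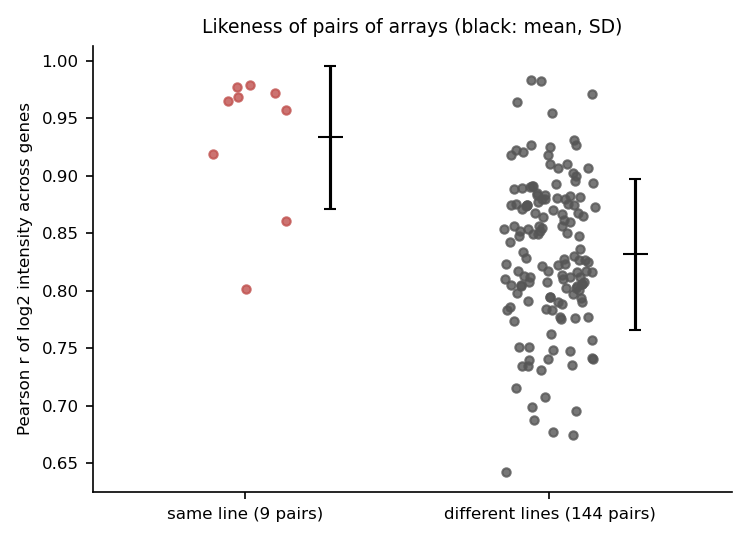
Pearson r of log2 intensity across genes (vertical axis) for pairs of arrays of one line (9 pairs, red) and of different lines (144 pairs, grey). Black marks are means and SDs, 0.933 ± 0.062 and 0.832 ± 0.065, and 2 same-line pairs lie below 0.9.

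The classical list showed how far arrays of a line could differ. Its mean level differed by 0.25 in the median line, but by 4.86 and 3.04 in the 2 lines with the widest differences, against an SD of 1.72 among line means. For the epithelial junction list the widest differences were 3.01 and 0.87, and for antigen presentation 0.76 and 0.48. Without the 2 lines whose arrays correlated below 0.9 the difference between groups was -2.21 for the classical list, -0.92 for the junction list and -0.73 for antigen presentation.

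Letters A and B were not called different for any gene. The test had 9 pairs, 2 of them unlike, so a difference between the letters is not excluded. In limma with the line as a block, 0 of 16887 genes had an adjusted p under 0.05 (smallest 0.9998), and 381 had an unadjusted p under 0.05.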

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

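Of 152 groups of line values, 11 held 1 value far from the others, where chance flags 1 in 20, or 7.6. The tests of the list pattern against other splits of the lines were set before their result was seen, and the other tests in this part were chosen after it.

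The 10 gene lists past the threshold, led by the classical, epithelial junction and antigen presentation lists, lay lower in sensitive lines by the preset camera test. Chance is not excluded: 23 of 100 splits of the 9 lines gave at least 10 lists (the real value 10, the highest other 14), and 64 of 100 splits gave at least 477 genes (highest other 2873). Members that vary together between lines may account for the calls, since camera with the correlation estimated from the data left 0 lists. Whether the 2 lines with unlike arrays account for part of the 10 cannot be told apart. Without them 5 passed, and 10 of the 36 pairs of lines left as few or fewer when left out (highest 14). The 3 leading lists still passed preset camera without these lines, so these calls did not need them. That test called a median of 7 lists in the other splits, so passing it again decides little. Without the 2 lines the exact permutation test gave p = 0.0571 for the classical list, 0.314 for the junction list and 0.0857 for antigen presentation (smallest possible 0.0286). A lower share of tumour cells cannot be told apart, because the classical minus junction difference (-0.90) had an exact permutation p of 0.183 with 9 lines, and a difference in tumour differentiation tied to the response stays open.

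In 2 lines the arrays did not match each other. Brightness before RMA was not tested, because the values at hand have all been through RMA. For the second least alike pair, an array that belongs to another line is a possible explanation, since its highest correlation with an array of another line was 0.983, above the lowest and the highest of the 7 alike pairs (0.919 and 0.978). However, 11 of 144 pairs of different lines, this one among them, lay above 0.919. The next highest of these were 0.982, above the highest alike pair, and 0.971, below it. For the least alike pair it cannot be told apart, because that correlation was 0.910, below 0.919 by less than the SD of those pairs (0.020). Tumours of one line that truly differ stay open, as the labels do not say how the arrays of a line are related.

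Among sensitive lines, BEX2 was 8.88 in 1 line and 5.69 to 6.60 in the others. SFN was 12.4 in 1 sensitive line and 11.2 to 11.4 in the others. PSEN2, a gamma-secretase subunit gene, was 6.04 in 1 non-sensitive line and 7.16 to 7.33 in the others.

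Each line value is the mean of 2 arrays, which were unlike in 2 lines. The classical list mean was 8.61 in 1 non-sensitive line and 10.5 to 10.7 in the others, and in the same line the ductal marker mean was 8.28, against 8.90 to 9.02 in the others. Its interferon mean was 7.93, against 6.54 to 6.73. The mesenchymal mean was 8.51 in 1 sensitive line and 6.30 to 6.77 in the others, and the ribosomal protein mean 11.4 in 1 sensitive line, whose arrays had the lowest mean intensities of the 18 (108 and 111), and 12.8 to 13.1 in the others. In 1 non-sensitive line the means of the Wnt list (5.86, against 6.25 to 6.26), the gemcitabine list (7.34, against 7.93 to 8.0) and the hypoxia list (7.94, against 9.06 to 9.19) were each below the others. That line, also the one with the low PSEN2 value, had arrays with 99th percentiles of intensity of 1331 and 1526, against 2138 to 2394 in its group.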

How the results depend on the processing

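The alternative without the 2 lines with unlike arrays was chosen after seeing the data, and the cause of the changes given here was not tested unless stated. The number of genes past limma's adjusted threshold stayed 0 in every alternative except the leave-one-out fits, where it ranged from 0 to 1. The count at an unadjusted p under 0.05 was 207 to 840 when 1 line was left out, 746 without the 2 lines, 785 with array A alone, 292 with array B alone, 1531 with array weights, 1394 with 18 arrays taken as independent, which counts each line 2 times, and 841 with every probe set tested, which tests more values. The count of lists was 4 to 11 when 1 line was left out, 5 without the 2 lines, 5 with array B alone, 0 with the estimated correlation, and 0 in fry, directional or mixed, which ask other questions. The excess correlation of same-line arrays was 0.325 with the 2000 most variable genes, which differ most between lines. The 24 named genes kept their sign in all 524 values, which their choice by no overlap fixes where lines are left out, and 0 of these passed. For the 10 lists, 118 of 160 values kept direction and call, 40 kept direction alone and 2 changed sign. The classical, epithelial junction and antigen presentation lists passed the preset camera test in 16 of 16 alternatives that used it. Reversals were of differences that had not passed, apart from the interferon list. When 1 line was left out, APH1A ranged from -0.65 to 0.13, PSENEN from -0.082 to 0.65, PSEN2 from -0.17 to 0.28, NCSTN from -0.25 to 0.20, the Notch target list from -0.13 to 0.057 and the interferon list from -0.46 to 0.0073. Without the 2 lines the interferon list stood at 0.097, the Notch target list at 0.0091 and the NF-kB target list at 0.022. With array A alone JAG1 stood at 0.044, APH1A at 0.18 and the Notch target list at 0.052. With array B alone PSENEN stood at -0.22, PSEN2 at -0.13 and NCSTN at -0.040, and with array weights PSEN2 stood at -0.11 and NCSTN at -0.15. No paired analysis was possible because the letters A and B mark arrays within a line and pair no lines between groups. The planned comparison of RNA integrity controls was not run, since the table held 0 control probe sets. Signal over background was not analysed here, and genes below the 30th percentile in most lines were left out of the tests.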

Other observations

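The test of the relation between lists in this part was chosen after its result was seen. Of the genes that varied most among the 9 lines, chosen after their values were seen, OLFM4, a marker of intestinal crypt cells, had an SD of 4.10 among line means on the log2 scale, with line means from 3.01 to 12.2, REG4 an SD of 3.78, the lysozyme gene LYZ 3.35 and the gastric claudin gene CLDN18 3.21. The chemokine gene CXCL5 (3.12), the intestinal keratin gene KRT20 (3.04), the squamous gene SPRR3 (3.04), GABRP (3.01) and CEACAM5 (2.98) followed. Between groups OLFM4 had a log2 fold change of 1.74 ± 2.35 (SE), REG4 of -4.30 ± 1.78 and CLDN18 of -4.07 ± 1.42, and each had an adjusted p of 0.9999 in limma.

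Classical and mesenchymal list means ran in opposite directions across lines. Over the 9 lines Pearson's r was -0.872 (exact permutation p = 0.00305, adjusted 0.00914 over 3 relations) and Spearman's rho -0.767 (exact permutation p = 0.0214). Without the 2 lines farthest from the median of the classical list r was -0.740 (exact permutation p = 0.0554), and without the 2 lines with unlike arrays it was -0.912 (exact permutation p = 0.0254). The larger p without the farthest lines comes with fewer lines as well as a weaker r. How far the relation rests on the farthest lines is therefore not settled. One candidate explanation is opposed differentiation states of the tumour lines, which these values leave open. The epithelial junction list had r = -0.802 with the mesenchymal list (exact permutation p = 0.0274, adjusted 0.0411, rho -0.550 with p = 0.133), but -0.097 (exact permutation p = 0.836) without the 2 lines farthest from its median, so that relation rests on them, and -0.863 (exact permutation p = 0.0675) without the 2 lines with unlike arrays. The classical and basal-like lists had r = 0.367 (exact permutation p = 0.333, adjusted 0.333, rho 0.533 with p = 0.148, r = -0.063 without the 2 lines farthest from the median, and r = 0.622 with exact permutation p = 0.136 without the 2 lines with unlike arrays).

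Probe sets without 1 gene name were tested too. Of 7529 such probe sets above the filter, 0 had an adjusted p under 0.05 in limma and 99 had an unadjusted p under 0.05.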
